A study of Caenorhabditis elegans with 10 samples.

How the data were processed

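Gene expression was measured on 10 Affymetrix arrays of the nematode Caenorhabditis elegans, 5 from the wild-type strain N2 and 5 from a mutant strain deficient in xpa-1. Each array was hybridised with total RNA of a separate collection of untreated worms of mixed stage, so that the replicates of a strain were separate collections and the spread between them holds both culture and array variation. Per the labels' protocols, worms grew at 20 degrees on agar with HT115(DE3) bacteria, were harvested from many plates by floating them on sucrose, and were broken with beads in TRIZOL, and the RNA was labelled with biotin by a 3' in vitro transcription kit.

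The deposited values are log2 probe set signals, 1 column per array. Per the submitters' processing notes the values came from Affymetrix Expression Console; the summary method, the background step and the scaling between arrays are not given in the sources used here. The file holds 22625 probe sets. Of the 134454 values below a log2 signal of 5, 100% were the log2 of a whole number within 0.005, so that the deposited signals had been rounded to whole numbers with a floor of 1, which is a log2 signal of 0. Over the tested probe sets 11.2% of all values stood at 0, and 421 probe sets were at 0 on all 10 arrays. A value of 0 is therefore the lowest value the file can hold, and of a gene with a strain's arrays all at 0 the text says only that it is listed at 0. Array medians lay between 4.00 and 4.25 in log2, and between 10.3% and 12.3% of an array's values were at 0. For arrays there is no read depth, and the number of arrays limits the precision.

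The 77 Affymetrix control probe sets were left out, which left 22548 for testing. The platform annotation gave 20766 of the tested probe sets 1 gene symbol, 887 several and 895 none. No gene was named from a probe set with several symbols. Symbols, chromosomes and the order of genes were looked up in the RefSeq gene table of assembly WBcel235, which held 17075 of the 17118 genes measured. Because the deposited file names no genome build, no coordinates are given, and the assembly served only for names, chromosomes and which genes neighbour each other.

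The deposited log2 values were used as they stand, with no further scaling and no filter on dim probe sets. The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05 on the adjusted p. For a count of genes, probe sets with 1 symbol were used, the probe set with the highest mean over all 10 arrays stood for its gene, and the adjustment was made over the 17118 genes. Differences are given as xpa-1 minus N2 in log2 with the standard error (SE) of the fit, and levels as mean ± standard deviation (SD) over 5 arrays. The xpa-1 transcript was also compared with an exact permutation test over all 252 ways of dividing the arrays. Gene lists were compared with limma's camera at a preset correlation of 0.01 between genes, two-sided, with adjustment over 36 lists of at least 3 measured members; an estimated correlation and limma's fry were run as alternatives.

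The sample groups, the tests, the 36 gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. The rule named xpa-1, then, among genes past the threshold whose 5 xpa-1 arrays all lay above or all below the 5 N2 arrays, up to 12 with the largest difference in each direction, and of each list described its members past the threshold or, where none passed, 1 or 2 of the brightest. The last part was applied only to lists described by their members, and lists given by their median alone have no member named. It named 10 genes that were higher and 9 that were lower. Other genes named in the text were chosen after their values were seen, and this is said where they appear.

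The comparison was tested on simulated data with 22548 probe sets, 5 arrays against 5 and the spread of the real arrays. For xpa-1 against N2, limma called 40% of probe sets changed by 1.5-fold, 80% of those changed by 2-fold, 98% at 4-fold and 100% at 8-fold, with 50 changed probe sets at each size. The changed probe sets were drawn only from those standing for a gene with a mean log2 signal over 4. The rates therefore do not cover dimmer probe sets. It called 179 probe sets in all, 17 of them not changed in the simulation. Members of a gene list that was shifted as a whole were left out of these 17. The adjusted threshold is easier to pass where more probe sets differ, and the real comparison called 22. The rates may therefore be too high for the real data, most of all for the smaller changes. In the same simulation camera called 1 list, the one that had been shifted. Genes were drawn independently of each other there. The simulation therefore cannot show how camera behaves where genes vary together, as the stage lists do between these arrays.

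The alternatives were quantile normalization, centring each array on its median, leaving out the dimmest 25% or 50% of probe sets, limma's trend and robust options, array weights, the replicate number as a block, germline list means as covariates, the mean of all probe sets of a gene, and each array left out in turn. Offsets of 16 and 64 on the unlogged signals, leaving out N2 replicates 1 and 5 together, and a fit with 3 stage covariates were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.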

Results

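The data describe the transcriptome of untreated, mixed-stage C. elegans that lack xpa-1, the nematode counterpart of the human XPA protein, which works in nucleotide excision repair. The mutant carries the deletion allele ok698 on chromosome I. The wild type is Bristol N2, the standard laboratory strain. Each strain was measured on 5 arrays, and the comparison asks which transcripts differ between the strains with no DNA-damaging treatment. Pairs of arrays of the same strain correlated across probe sets with r from 0.953 to 0.984 (median 0.971), and pairs of arrays from different strains with r from 0.959 to 0.979 (median 0.973), where the correlation is across probe sets, which are not independent replicates.

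The xpa-1 transcript (K07G5.2, chromosome I) was measured first, since it checks the strain labels. Its log2 signal was 6.62 ± 0.19 (SD, n = 5) in N2 and 0.72 ± 0.70 (SD, n = 5) in the mutant. The 5 N2 arrays lay between 6.38 and 6.88 and the 5 mutant arrays between 0 and 1.58, in the order the labels give. The difference was -5.90 (SE 0.304, limma adjusted p = 5.17e-05), and the exact permutation test, two-sided, gave p = 0.00794, the smallest p that 5 arrays against 5 can reach. Where the probes of this probe set lie against the ok698 deletion is not given in the sources used here, so the low signal shows loss of the probed part of the transcript. The size of the fall depends on the lowest values of the scale, and with an offset of 16 on the unlogged signals, chosen after seeing the data, the difference was -2.69.

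Few transcripts differed between the strains. Of 17118 genes, 19 passed the threshold in limma, 10 higher and 9 lower in xpa-1, and 570 had an unadjusted p under 0.05. Of the 19 genes, 16 differed by 2-fold or more and 6 by 4-fold or more. Over probe sets, 22 of 22548 passed, 12 higher and 10 lower, with 734 at an unadjusted p under 0.05. Both counts at an unadjusted p under 0.05 are smaller than a share of 0.05 of those tested. They show no excess of weaker differences, but counts below that share cannot show that weaker differences are absent. Centring each array on its median also called 19 genes, divided into 8 higher and 11 lower. These were not all the same genes, since rnh-1.3 and fbxa-122 were lost there (limma adjusted p = 0.057 and 0.205). None of the 19 genes of the main comparison belonged to the 36 gene lists, which held 1257 measured genes. However, xpa-1, itself a repair gene, had been left out of the lists when they were drawn up.

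Among genes, the largest changes were in 5 besides xpa-1. The probe sets that passed are not all those of the 19 genes. A probe set of grdn-1 that does not stand for its gene passed (difference -1.12, SE 0.116, limma adjusted p = 0.00817). It was close to the floor in both strains, and is named after its values were seen. The probe set of fbxa-122 passed over genes only (limma adjusted p = 0.054 over probe sets). Of the probe sets that passed, 3 had no gene symbol or several and lie outside the gene count. A probe set without a symbol among these 3 rose from 1.35 ± 0.94 to 5.23 ± 0.63 (SD, n = 5 each). That is a difference of 3.88 (SE 0.475, limma adjusted p = 0.0213). The transcript of bcf-1 (F57F4.4, chromosome V) fell from 10.30 ± 0.12 in N2 to 2.04 ± 0.31 in xpa-1 (SD, n = 5 each), a difference of -8.25 (SE 0.143, limma adjusted p = 7.79e-09), or 305-fold. The neighbouring gene gfi-1 (F57F4.3), whose product was named for its interaction with the GEI-4 protein, rose from 7.96 ± 0.55 to 11.64 ± 0.15, a difference of 3.68 (SE 0.242, limma adjusted p = 0.000221), or 12.8-fold. Next to xpa-1 on chromosome I, mks-6 (K07G5.3), which encodes a protein of the transition zone at the base of the cilium, rose from 1.90 ± 0.63 to 6.98 ± 0.13, a difference of 5.08 (SE 0.27, limma adjusted p = 5.17e-05), or 33.9-fold. Y102A5C.6 on chromosome V fell from 6.74 ± 0.15 to 2.75 ± 0.43, a difference of -3.99 (SE 0.196, limma adjusted p = 5.17e-05), or 15.9-fold. The gfi-1 and bcf-1 probe sets are of the array's class whose probes can match several related transcripts. ZK105.5, also on chromosome V, rose from 0.40 ± 0.55 to 2.79 ± 0.28, which is dim in both strains. Folds against a dim strain depend on the low end of the scale: with the offset of 16 the bcf-1 difference was -5.98 and that of mks-6 was 2.83.

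**Figure D1:**
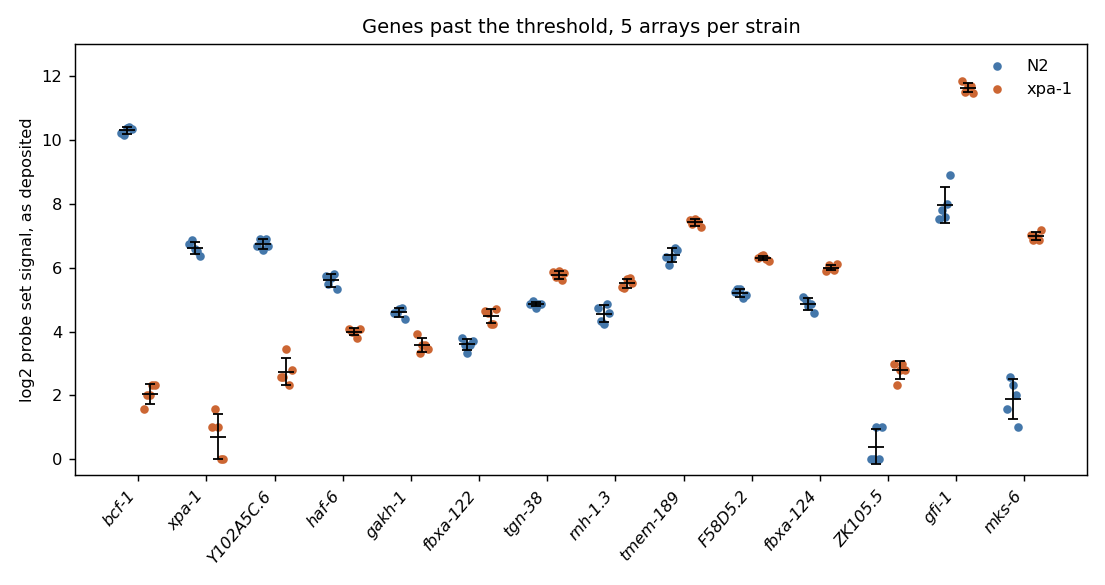
Log2 probe set signal, as deposited, of the 14 genes past the threshold with a strain mean of 2 or more, with 1 point per array (blue N2, orange xpa-1), a horizontal mark at the mean and bars of 1 SD (n = 5 per strain). The genes were selected for differing on these arrays; for bcf-1, N2 lies between 10.14 and 10.41 and xpa-1 between 1.58 and 2.32.

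Genes of intermediate level changed by about 2-fold to 3-fold. The half-molecule ABC transporter gene haf-6, which is needed for efficient RNA interference, fell from 5.60 ± 0.20 to 4.00 ± 0.11 (difference -1.61, SE 0.104, limma adjusted p = 0.000221). The gene gakh-1, a homologue of the cyclin G-associated kinase of vesicle uncoating, fell from 4.60 ± 0.14 to 3.57 ± 0.22 (difference -1.03, limma adjusted p = 0.00984). On chromosome I, 5 genes rose by 0.89 to 1.14 in log2. They were the F-box genes fbxa-124 (4.87 ± 0.20 in N2, and between 5.91 and 6.11 on the xpa-1 arrays) and fbxa-122 (3.60 ± 0.18 to 4.48 ± 0.22), F58D5.2 (5.21 ± 0.12 to 6.31 ± 0.07), tmem-189, a homologue of the plasmalogen desaturase (6.39 ± 0.22 to 7.42 ± 0.11), and rnh-1.3 of the RNase H family (4.55 ± 0.27 to 5.52 ± 0.14), with n = 5 arrays per strain. Their limma adjusted p values ran from 0.000221 for F58D5.2 to 0.0496 for fbxa-122. The calls of fbxa-122 and rnh-1.3 were the least secure, since the call of fbxa-122 was lost when any 1 array was left out and that of rnh-1.3 when any 1 array except N2 replicate 4 was. The trans-Golgi gene tgn-38 on chromosome IV rose by 0.92 (4.86 ± 0.07 to 5.78 ± 0.12, limma adjusted p = 0.000674), but its other probe set differed by -0.47 (SE 0.161, unadjusted p = 0.0168 in limma, adjusted p = 1), so the probe sets of this gene disagree and their mean did not pass. The call of gakh-1 was lost without N2 replicate 3, and that of tmem-189 without N2 replicates 1 and 5 together, a setting chosen after seeing the data.

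The remaining 5 genes were close to the floor in both strains. The N2 means of Y41G9A.6, irld-16, C25F6.6 and the chemoreceptor gene srg-7 were 1.46, 1.43, 1.35 and 1.43 in log2, and all 5 xpa-1 arrays were listed at 0 for each of them. Y49F6C.6 was listed at 0 on all N2 arrays and had a mean of 1.23 in xpa-1. Their limma adjusted p values ran from 0.000807 for Y41G9A.6 to 0.0255 for irld-16 and srg-7. No call of these 5 genes held with an offset of 16 or with limma's trend and robust options, and single arrays ended some of them: srg-7 and irld-16 were lost without any 1 xpa-1 array and without N2 replicate 3, srg-7 also without N2 replicate 4, irld-16 without N2 replicate 2, and Y49F6C.6 without N2 replicate 3.

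Several of the genes that differed lie side by side in the gene order of assembly WBcel235. These are xpa-1 and mks-6, gfi-1 and bcf-1, and fbxa-124 and fbxa-122. Around fbxa-124, a run of 5 adjacent measured genes was higher in xpa-1: tmem-189 by 1.03 (SE 0.11), Y53C10A.6 by 0.85 (SE 0.169), fbxa-124 by 1.14 (SE 0.099), fbxa-122 by 0.89 (SE 0.126) and fbxa-123 by 0.82 (SE 0.139). The probe sets of tmem-189, fbxa-122 and fbxa-123 are also of the class whose probes can match several related transcripts, as are those standing for F58D5.2 and gakh-1. The other probe set of F58D5.2, not of that class, differed by 1.16 (SE 0.222, unadjusted p = 0.000504 in limma, adjusted p = 0.367). Y53C10A.6 and fbxa-123 did not pass the threshold (limma adjusted p = 0.385 and 0.173) and were chosen after their values were seen. So were the flanking genes, where rga-2 differed by -0.09 and Y53C10A.1 by 0.10 on 1 side and the dim abt-5 by 0.43 on the other. Further along that side several genes were also above 0 without passing the threshold, among them F58D5.7 by 0.37 (SE 0.34), F58D5.6 by 0.63 (SE 0.356), F58D5.5 by 0.40 (SE 0.3) and ksr-2 by 0.42 (SE 0.328), while the dim Y53C10A.10 differed by -0.20 (SE 0.191). F58D5.2 lies 11 measured genes from fbxa-124, and hrpr-1 next to it differed by 0.15 (SE 0.078).

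**Figure D2:**
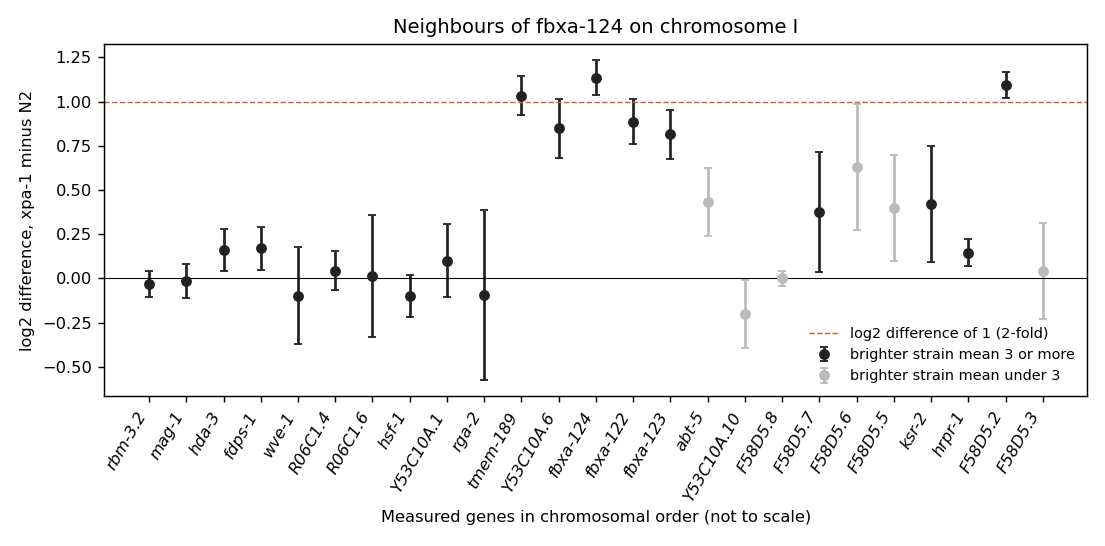
Log2 difference (xpa-1 minus N2) of measured genes in their order on chromosome I around fbxa-124, not to scale, with bars of 1 SE (n = 5 arrays per strain), where grey points are genes with a mean log2 signal under 3 in both strains and the dashed line marks a 2-fold difference. The genes from tmem-189 to fbxa-123 lie between 0.82 and 1.14, the measured genes to the left of them between -0.10 and 0.17, and those to the right, up to hrpr-1, between -0.20 and 0.63.

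DNA repair genes other than xpa-1 did not differ as groups. Of 20 measured genes of nucleotide excision repair and the transcription factor TFIIH, with xpa-1 left out of the list, 0 passed the threshold over all genes and 0 adjusted over the list alone, 0 had an unadjusted p under 0.05 in limma, and the median difference was 0.04 (camera in limma, adjusted p = 0.948). Among them, rad-23, a partner of the damage sensor XPC, had a log2 signal of 8.71 ± 0.27 in N2 and 8.71 ± 0.12 in xpa-1, and rpa-2, a subunit of the single-strand binding protein RPA, 8.42 ± 0.24 and 8.49 ± 0.12. Base excision repair (9 genes) had a median difference of 0.03, with the sliding clamp gene pcn-1 at 9.43 ± 0.25 in N2 and 9.46 ± 0.14 in xpa-1. Other repair and DNA damage response genes (39 genes) had a median of 0.05, with the ribonucleotide reductase gene rnr-2 at 9.95 ± 0.24 and 10.03 ± 0.12. Most members of this list had a difference above 0, but the list did not pass camera in limma.

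Apart from the osmotic and wounding response, the stress response and detoxification lists did not pass either, and over all 36 lists 0 members passed in limma, whether adjusted over all genes or adjusted over the list alone. The antioxidant enzymes (27 genes) had a median difference of 0.08, with the peroxiredoxin gene prdx-2 at 10.53 ± 0.06 in N2 and 10.48 ± 0.07 in xpa-1 and the glutathione reductase gene gsr-1 at 9.43 ± 0.04 and 9.41 ± 0.07. Median differences were -0.02 for SKN-1 targets, -0.01 for glutathione S-transferases, 0.10 for cytochrome P450s and -0.03 for heat shock proteins, where the small heat shock protein gene sip-1 stood at 11.65 ± 0.14 and 11.72 ± 0.12. The unfolded protein responses of the endoplasmic reticulum and of mitochondria had medians of 0.04 and 0.002, the class I and class II targets of DAF-16 0.08 and -0.01, and the insulin signalling pathway 0.02. The medians were 0 for innate immune effectors and C-type lectins, 0.03 for lysozymes, 0.08 for the hypoxia response, 0.01 for the fasting response and -0.002 for UDP-glucuronosyltransferases.

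Of the 36 lists, 2 passed camera in limma. The osmotic and wounding response list was higher in xpa-1, with a median difference of 0.16 over 12 genes (camera in limma, adjusted p = 0.0385), a call that was lost with an estimated correlation (adjusted p = 0.993, unadjusted p = 0.0643). Its members include lea-1, a gene linked to desiccation tolerance, at 9.52 ± 0.43 in N2 and 10.04 ± 0.24 in xpa-1, and the glycerol-3-phosphate dehydrogenase gene gpdh-2 at 8.44 ± 0.06 and 8.46 ± 0.08. Not all members rose. Of members chosen after their values were seen, gpdh-1 differed by 0.01 (SE 0.162), hmit-1.1 by -0.11 (SE 0.298) and cnc-4 by 0.62 (SE 0.208). The body wall and pharyngeal muscle list was lower, with a median of -0.10 over 28 genes, 26 of them negative (camera in limma, adjusted p = 0.0169), and this call too was lost with an estimated correlation (adjusted p = 0.993, unadjusted p = 0.345). Its brightest members were the myosin light chain gene mlc-2 at 11.28 ± 0.09 and 11.17 ± 0.25, and the troponin C gene pat-10 at 11.01 ± 0.07 and 10.99 ± 0.08. For both lists fry in limma gave adjusted p = 0.999. The osmotic list was lost without N2 replicate 1 or 3 or any 1 xpa-1 array, and the muscle list without N2 replicate 3 or 5 or xpa-1 replicate 2 or 5 (adjusted p from 0.061 to 0.173 and from 0.104 to 0.698 in limma). Single arrays also moved the medians: that of the osmotic list was 0.05 without N2 replicate 1, and that of the muscle list was -0.04 without N2 replicate 5, -0.03 without xpa-1 replicate 2, -0.02 without xpa-1 replicate 5 and -0.16 without xpa-1 replicate 3. The muscle list was also lost with array weights (adjusted p = 0.198 in limma) or the oocyte list as a covariate (0.213). The osmotic list was also lost with the mean of all probe sets of a gene (adjusted p = 0.0587 in limma) or with replicate number as a block (0.133).

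Apart from muscle, the metabolic, tissue and stage lists did not pass. Oxidative phosphorylation had a median difference of -0.03 over 35 genes (camera in limma, adjusted p = 0.0675), cytosolic ribosomal proteins 0.002, proteasome subunits 0.02, fatty acid synthesis 0.005, glycolysis and related pathways 0.03, and histones 0.01. Vitellogenins, the yolk proteins, had a median of 0.01, the intestine list 0.01, and the neuron list 0.004. The early zygotic list had a median of 0.05 and the sperm genes outside the major sperm protein family -0.02. For 13 of the 36 lists the median, the mean and the direction of the test did not all share a sign, and 0 of these passed.

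The stage lists differed far more between arrays of a strain than between strains. Major sperm protein genes had a list mean of 9.57 ± 1.03 (SD, n = 5) in N2 and 9.56 ± 0.44 (SD, n = 5) in xpa-1, and the 10 arrays ranged from 8.01 to 10.62, or 6.13-fold. These genes are near-identical copies, so their probe sets can share transcripts. The molting cycle list had means of 5.67 ± 0.50 and 5.65 ± 0.40 and a range of 2.52-fold, and the collagens, the main cuticle proteins, a range of 1.97-fold with a median difference of -0.01. The oocyte and maternal germline list had means of 9.02 ± 0.27 and 9.09 ± 0.14, with the eggshell gene cpg-2 at 11.06 ± 0.08 and 11.06 ± 0.11.

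**Figure D3:**
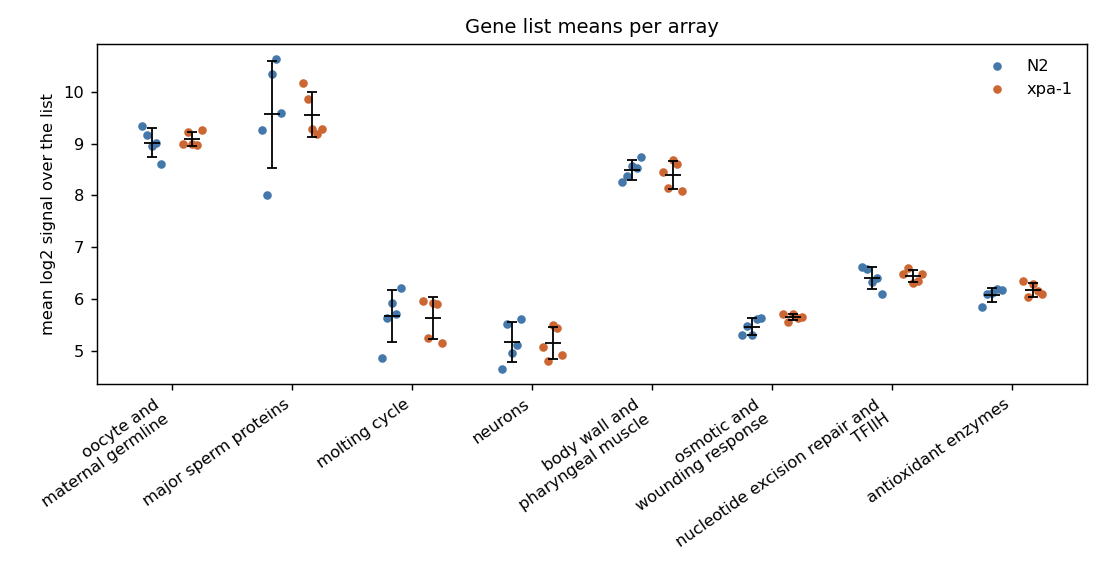
Mean log2 signal of 8 gene lists on each array (1 point per array, blue N2, orange xpa-1), with a horizontal mark at the strain mean and bars of 1 SD (n = 5 per strain). The strains overlap in every list shown, and the widest range is that of the major sperm proteins, from 8.01 to 10.62.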

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

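In this part, the tests of F-box cross-hybridisation, of probes shared by adjacent F-box genes, of an extra copy, of the run in standard errors, of gfi-1 with 3 stage covariates, of bcf-1 measuring gfi-1 and of a wider change around xpa-1 were chosen only after the result was seen.

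A test for a single array far from the other 4 of its strain was run on 110 groups of 5 values and found 6, where chance gives about 1 in 20. ZK105.5 read 2.32 in xpa-1 replicate 2 against 2.81 to 3 on the other mutant arrays. Y41G9A.6 read 1 in N2 replicate 5 against 1.58 on the other N2 arrays, at the lowest steps of the scale. In N2 replicate 1, the list mean of the antioxidant enzymes was 5.85 against 6.11 to 6.19, that of glutathione S-transferases 4.53 against 4.72 to 4.79, and that of the DAF-16 class II targets 5.17 against 5.56 to 5.72. In N2 replicate 5 the vitellogenin list mean was 10.88 against 11.36 to 11.52.

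The number of calls was set against other divisions of the 10 arrays into 5 and 5, of which 100 were drawn, the real one included. For probe sets, 1 of 100 gave as many (22, highest other 15), and for genes 2 of 100 (19, highest other 21), so that chance division is excluded at the 5% level for both. For gene lists, 90 of 100 gave as many as the real 2 (highest other 25), so that chance is not excluded for the lists past the threshold.

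The run of 5 adjacent genes on chromosome I from tmem-189 to fbxa-123 was higher in xpa-1, with a weighted mean difference of 0.985 (95% interval 0.877 to 1.092, or 1.84-fold to 2.13-fold) over the 5 genes. This interval treats the 5 genes as independent. They were measured on the same arrays and some may share probes, so the interval may be too narrow. In 23 of 100 divisions some window of 5 genes had as large a median difference (0.886, highest other 1.5), so chance is not excluded by size, but in units of standard error 1 of 100 did (7.043, highest other 4.87). Cross-hybridisation within the F-box family is not decided by tmem-189, no F-box gene, which rose by 1.034. That gene was placed in the run for being higher, and its probe set can itself match several related transcripts. The 168 other measured fbxa genes had a median difference of 0.009, with 0 past the threshold. For fbxa-122, fbxa-123 and fbxa-124, probes shared between the 3 adjacent genes cannot be told apart from separate changes. Of their 3 probe sets, 2 are of the class that can match several related transcripts. Whether the mutant strain carries an extra copy of the segment cannot be told apart from other causes, because the interval, which holds 2-fold, was computed on genes chosen for being higher. Regulation shared by neighbours and a variant from the strain's history were not tested.

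The opposite changes of the neighbours gfi-1 and bcf-1 on chromosome V were weighed next. A difference in developmental stage, as far as the 3 stage lists capture it, is argued against by their near-equal means in the strains. With these 3 lists as covariates the gfi-1 difference was 3.865 against 3.68 without them. Because the covariates barely differed between the strains, that fit had little room to change the difference and adds little. That the bcf-1 probe set also measures the gfi-1 transcript is argued against by its highest log2 signal on the mutant arrays, 2.32, where gfi-1 lies between 11.47 and 11.83. Of the neighbours, chosen after their values were seen, the dim cht-6 next to bcf-1 differed by 0.86 (SE 0.554) and F57F4.1 next to gfi-1 by 0.05 (SE 0.454), neither past the threshold. A rearrangement of the DNA at this place may account for both changes, which was not tested; a sequence variant under the probes, which lowers signal, stays open for the fall of bcf-1 and not for the rise of gfi-1.

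The rise of mks-6 beside the deleted gene was weighed last. More ciliated neurons in the mutant cultures are argued against by 52 other cilium genes, whose median difference was -0.065 (quartiles -0.237 and 0.171, 0 past the threshold), and among the 15 of them with a mean log2 signal over 3 the median was 0.074. A wider change of transcription around xpa-1 is argued against by the 10 nearest other measured genes, with a median of 0.022 and a range of -0.14 to 0.168. A local effect of the ok698 deletion on its neighbour, such as transcription that runs on into mks-6, may account for the rise, which was not tested, and loss of the XPA protein itself also remains open.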

How the results depend on the processing

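Of the settings reported here, the offsets of 16 and 64, the fit without N2 replicates 1 and 5 together and the fit with 3 stage covariates were chosen only after the data were seen. The differences followed through the settings were those of the 19 genes and of the 2 lists past the threshold. None of these changed direction under any setting run. The calls of bcf-1, F58D5.2, mks-6 and Y102A5C.6 held in 24 of 24 alternatives, and that of xpa-1 in every alternative that kept it; leaving out the dimmer 50% of probe sets removes xpa-1. The calls of gfi-1, haf-6, fbxa-124 and ZK105.5 were lost under the replicate block and under no other setting that kept the gene, and that of tmem-189 also without N2 replicates 1 and 5. Same-numbered arrays of the strains do not deviate together (r from -0.26 to -0.01), so the numbers do not pair the samples; with replicate number as a block 2 probe sets, 5 genes (5 shared with the 19) and 1 list passed. Without the dimmer 50% of probe sets 12 probe sets and 11 genes passed (11 shared), where fewer were tested, and with an offset of 64 there were 14 probe sets. With an offset of 16, 13 genes passed, all among the 19, and without N2 replicates 1 and 5 together 25 probe sets and 23 genes, 15 of them among the 19. Leaving out 1 array gave 14 to 26 probe sets, lowest without N2 replicate 3, 13 to 21 genes, and 0 to 7 lists: 6 without N2 replicate 1, 7 without N2 replicate 2, 4 without xpa-1 replicate 1, 1 without xpa-1 replicate 4, and 0 without N2 replicate 3 or xpa-1 replicate 2 or 5. List counts were 1 with the mean of all probe sets of a gene, 0 with an estimated correlation, 0 with fry, 0 without N2 replicates 1 and 5, and 4 with 3 stage covariates. The xpa-1 difference ran from -6.12 to -5.725 with 1 array left out, and was -2.686 and -1.306 with offsets of 16 and 64, which shrink differences of dim probe sets by construction. Apart from these stated ones the cause was not tested. The offsets planned in case the values were linear were not run as planned, because the deposited values are logs, and the offsets of 16 and 64 on the unlogged signals were added instead. Signal near the floor limits the 5 genes with both strain means under a log2 of 2.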

Other observations

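The 3 relations between stage lists and the count of neighbouring genes described here were chosen only after the data were seen.

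Germline and larval lists varied in opposite directions between cultures of either strain. Over the 10 arrays the mean of the oocyte and maternal germline list was lower where the mean of the molting cycle list, a larval signature, was higher (Pearson's r = -0.92, permutation p = 1e-05, the smallest the permutations can give, adjusted 3e-05; Spearman's rho = -0.94, permutation p = 0.00021, adjusted 0.00063). The relation was -0.96 without the 2 arrays farthest from the median and -0.92 within strains. The oocyte list and the major sperm proteins were not related beyond chance (r = -0.29, permutation p = 0.411; rho = -0.32, permutation p = 0.368). The molting and neuron lists were related by Pearson's r and not, at the same threshold, by Spearman's rho (r = 0.76, permutation p = 0.0122, adjusted 0.0183; rho = 0.62, permutation p = 0.0604, adjusted 0.0906), with r = 0.57 without the 2 farthest arrays and 0.76 within strains.

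Adjacent genes were more frequent among the calls than a random scatter gives. The 19 genes held 3 adjacent pairs in the order of 17067 measured genes, against at most 1 in 10000 random sets of as many genes (permutation p = 1e-04, the smallest the sets can give). On chromosome I, which holds 2469 of the measured genes, lay 8 of the 19, against 2.7 expected at an equal rate (Fisher's exact test, p = 0.0032, with genes that are not independent). Without fbxa-122 and rnh-1.3, whose calls were lost when most single arrays were left out, 17 genes held 2 pairs (highest random set 2, permutation p = 2e-04) and 6 lay on chromosome I against 2.5 expected (Fisher's exact test, p = 0.027). All these counts were made after the pairs had been seen, and 1 pair holds xpa-1 itself. Another pair, fbxa-124 and fbxa-122, may share probes, which the random sets do not allow for. Both counts on chromosome I hold xpa-1, whose place and call came with the choice of strain, and its neighbour mks-6. They also count tmem-189 and fbxa-124, of the same run, as separate genes. Fisher's exact test therefore cannot show an excess on chromosome I apart from xpa-1 and these groups of neighbours. Whether the changes come from loss of xpa-1 or from DNA linked to it or carried along in the strain was not tested, and would need other data, such as another xpa-1 allele or the strain's genome sequence.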
